A study of Mus musculus with 3 samples.

How the data were processed

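RNA-seq of total RNA was analysed for 3 libraries of F121-9, a hybrid mouse embryonic stem (ES) cell line whose parents are of the Cast and 129 strains. The labels name the libraries as biological replicates 1 to 3 at passage 14, each from 400 ng of RNA, and they form 1 group. No comparison between groups exists, and p-values measure the spread between these 3 libraries, which may be technical.

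For each library 1 gene table and 2 transcript tables were used, on mm10 with the GENCODE M21 annotation per the file headers and notes. The gene table and the first transcript table have the columns that RSEM writes and were made from transcriptome alignments, per the notes deposited with the libraries; they are called RSEM-style here. The second transcript table has the columns that kallisto writes and was made from the read files with no alignment file; it is called kallisto-style. The quantifiers, the aligner, their versions and the strand setting are not given in the sources used here. The deposited estimated counts (expected counts) are per gene or transcript and not normalized. The deposited TPM values were scaled to the same sum in each library over all features, spike-ins included. FPKM and posterior columns were not used. All 55536 Ensembl gene IDs matched the M21 annotation, from which symbols, types and coordinates were taken. For 3 listed symbols with more than 1 gene ID, the ID of highest mean TPM was used.

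In replicates 1, 2 and 3 the RSEM-style tables held 10610782, 9765384 and 10175403 estimated counts in all, and 19156106, 17717726 and 18471552 estimated counts stood in the kallisto-style ones. A count of 0 allows up to 3 counts, or 0.283, 0.307 and 0.295 CPM (counts scaled to library size) in the 3 libraries, which covers counting error only. The labels name ERCC and Lexogen SIRV spike-ins; 96 ERCC rows were analysed, and SIRVs were not analysed here. A further 26248 rows that carry tRNA numbers in place of gene IDs took 0.000147% of the counts on average. These rows and the spike-ins were kept out of library sizes and tests.

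Counts were rounded to whole numbers. Genes variable between replicates were sought with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): filterByExpr, TMM and an intercept-only quasi-likelihood fit, each gene's dispersion being set against the trended prior by the F distribution with Benjamini-Hochberg adjustment at 0.05. Spread beyond counting noise was tested with a chi-square test against Poisson with 2 degrees of freedom on the same genes. The transcript tables of each library were compared with limma on the difference of log2(TPM + 1), for transcripts with TPM of at least 1 in either table in all 3 libraries. Calls needed an adjusted p under 0.05 and a mean difference of at least 1, and such differences understate the change of low transcripts. Differences between lists were tested with an exact two-sided sign-flip permutation test over the libraries. Other values came from Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

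The scripts were tested on simulated data. Among 13391 genes drawn from the real means, with 50 genes of over 5 CPM changed in 1 library at each fold, the variable gene test recovered 2% at a fold of 1.5, 40% at 2, 94% at 4 and 100% at 8, with 0 false calls. The simulated dispersion was set below the common dispersion of the real counts (0.00303), and no library stood apart from the others. Recovery may therefore be lower in the real data, and the 0 false calls do not cover a library that stands apart. The transcript test recovered 100% of transcripts changed by a log2 difference of 1.25 to 3 among 23378, with 0 false calls. Its simulated tables differed otherwise only by random noise far below the minimum difference of 1, so the 0 false calls followed from the settings. Reads shared between transcripts and effective lengths of 0 were not simulated, so real calls that arise from them are not covered.

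Before the data were examined, 27 gene lists were fixed: core pluripotency, naive pluripotency, formative and primed, neuroectoderm, mesoderm and primitive streak, endoderm, trophoblast, fibroblast (feeder cells), 2-cell-like, germline, imprinted, X inactivation centre, Y chromosome, DNA methylation, Polycomb, cell cycle, LIF and STAT3, FGF and ERK targets, WNT targets, glycolysis, p53 and stress, housekeeping, abundant noncoding, replication-dependent histones, ribosomal proteins, mitochondrial genome and ERCC spike-ins. The genes named are the 10 of highest mean TPM, members of each list among the 4 highest and the lowest, Pou5f1, Sox2, Nanog, Zfp42, Fgf5, Otx2, Xist and Tsix, the variable genes, the 5 transcripts of largest difference in each direction, and isoforms of 12 genes fixed in advance. Some items that this rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen. A gene was called expressed with TPM of at least 1 in all 3 libraries.

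Alternatives were other thresholds, pseudocounts of 0.1, RLE factors, no filter, limma-voom, the edgeR legacy fit, ERCC scaling, the kallisto-style tables, all gene types and leaving out each replicate. Kallisto-style counts in the count tests, centred differences, a minimum length of 300 nt and an effective length above 0 were added after seeing the data.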

Results

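The transcriptome of F121-9 mouse ES cells was measured in 3 libraries labelled as biological replicates, which form 1 group. Gene values are RSEM-style TPM, given as the mean ± SD of n = 3 libraries unless stated, with coordinates on mm10. The libraries held 9765384 to 10610782 estimated counts. Of 55536 genes, 13113 reached a TPM of at least 1 in all 3 libraries, and 11478 of these were protein-coding.

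Dppa5a is an RNA-binding protein gene of pluripotent cells (ENSMUSG00000060461.5, chromosome 9, 78367052 to 78368177). It was the most abundant gene in the RSEM-style tables at 26198 ± 1726 TPM. In the kallisto-style tables Dppa5a stood at 17287 ± 367 TPM, below the mean of the microRNA gene Mir6236 (22976 ± 8821 TPM, an uncertain value). It also lay below the microRNA transcripts Gm24270-201, Gm24245-201 and Gm23935-201 (22392 ± 9550 TPM each, uncertain too). Next in the RSEM-style tables were the mitochondrial ATP synthase genes mt-Atp8 and mt-Atp6 at 8091 ± 325 and 6767 ± 167 TPM. The ferritin light chain gene Ftl1 stood at 5977 ± 311 TPM and its near copy Ftl1-ps1 at 4192 ± 209 TPM (2759 ± 30.7 in the kallisto-style tables), a pair whose reads cannot be split with certainty. Rpl41, Ppia, Rps27 and Rps14 were also among the 10 most abundant genes of the RSEM-style tables, between 3687 and 4676 TPM. Ribosomal protein genes took 13.2 ± 0.0816% of all TPM, with 88 of 89 members expressed and Rpl32l lowest at 0.723 ± 0.692 TPM. In the mitochondrial genome 14 of 37 genes were expressed, together 2.595 ± 0.0648% of TPM, and mt-Nd4l had 0 counts in the RSEM-style tables. The 22 transfer RNAs of this list have an effective length of 0 in the RSEM-style tables, which therefore cannot give them a value. In the kallisto-style tables all 37 were expressed, with mt-Nd4l at 535 ± 38.9 TPM, so its 0 in the RSEM-style tables does not show absence.

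Pluripotency genes lay far above markers of the germ layers and of trophoblast. All 10 core pluripotency genes were expressed. Among them Trim28, a corepressor gene, reached 702 ± 26.8 TPM, the transcription factor gene Nanog (ENSMUSG00000012396.12, chromosome 6, 122707489 to 122714633) 505 ± 10.9 TPM, Pou5f1, which encodes OCT4 (ENSMUSG00000024406.16, chromosome 17, 35506018 to 35510772), 495 ± 100.4 TPM, and Tdgf1, a NODAL co-receptor gene, 398 ± 16.2 TPM. In the kallisto-style tables Trim28 stood at 403 ± 41.8 TPM, below Nanog at 437 ± 16.5. Sox2 stood at 279 ± 29.8 TPM and Lin28a was lowest at 26.5 ± 1.76 TPM. Of the 12 neuroectoderm genes 3 were expressed, Tubb3 at 10.6 ± 1.88, Nes at 5.34 ± 0.924 and Map2 at 3.71 ± 0.823 TPM. Of the 11 mesoderm and primitive streak genes 3 were expressed, Gsc at 8.90 ± 0.484, T at 4.86 ± 1.70 and Eomes at 1.85 ± 0.524 TPM. The endoderm list had 3 of 11 expressed, led by Gata4 at 1.87 ± 0.0872 TPM. The trophoblast list had 2 of 9 expressed, Ascl2 at 3.68 ± 0.364 and Krt7 at 1.99 ± 0.192 TPM, with Krt7 at 6.76 ± 0.434 and Ascl2 at 2.91 ± 0.746 TPM in the kallisto-style tables. Dcx, Hand1, Ttr and Tpbpa had 0 counts in all 3 libraries. The median log2(TPM + 1) of the core list exceeded that of the 43 genes of the 3 germ layer lists and the trophoblast list by 7.26 ± 0.116, in 3 of 3 libraries (exact sign-flip permutation test, two-sided, p = 0.25, the smallest p that 3 libraries allow).

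**Figure D1:**
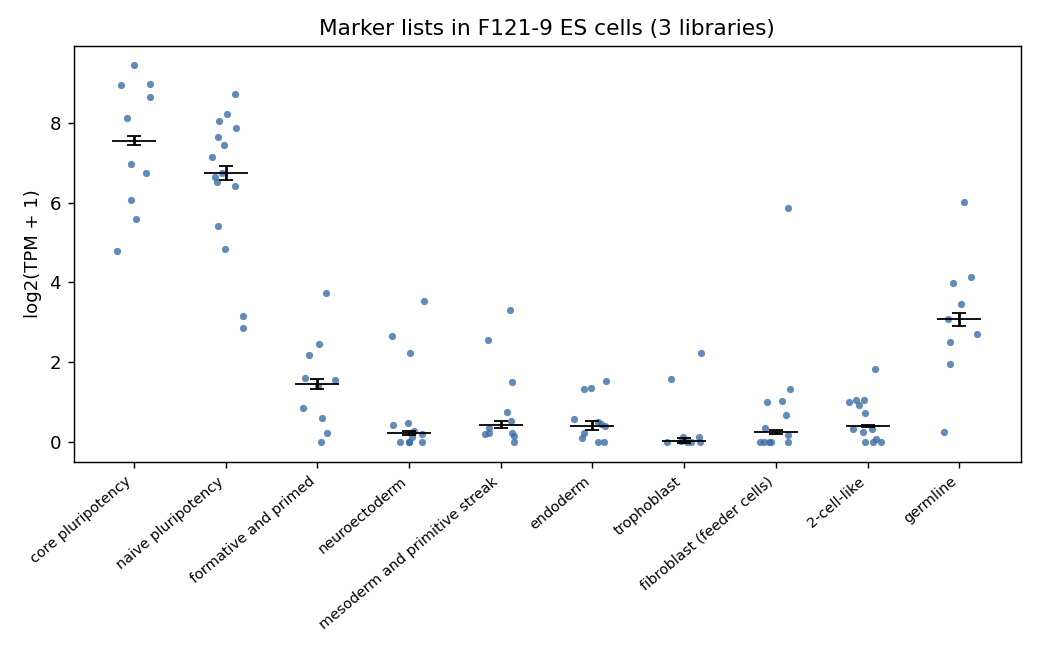
Level of each member of 10 marker lists (points, mean of 3 libraries, log2(TPM + 1) on the vertical axis) by list on the horizontal axis; bars give the mean and SD over libraries of the list median. Core and naive pluripotency medians, 202 and 107 TPM, lie above those of the germ layer lists, and Fbln1 at 57.7 TPM stands alone among the fibroblast genes.

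The median of the naive list lay above that of the formative and primed list, although single genes overlapped. All 15 naive genes were expressed: Zfp42, the REX1 gene (ENSMUSG00000051176.6), at 425 ± 4.24 TPM, Klf5 at 296 ± 11.1, Klf2 at 262 ± 12.7 and Tcl1 at 234 ± 5.69, with Nr5a2 lowest at 6.28 ± 0.827. Of the 10 formative and primed genes 6 were expressed. The de novo DNA methyltransferase gene Dnmt3b led them at 12.3 ± 1.88 TPM, followed by Otx2 at 4.50 ± 0.516, Lef1 at 3.55 ± 0.327 and Cdh2 at 2.06 ± 0.379. Fgf5, a marker of the post-implantation epiblast, stood at 0.170 ± 0.142 TPM on 4 counts in total (0.104 ± 0.0651 TPM in the kallisto-style tables), and Wnt8a had 0 counts. The list medians differed by 5.29 ± 0.268 on the log2(TPM + 1) scale, in 3 of 3 libraries (exact sign-flip permutation test, two-sided, p = 0.25, again the smallest possible).

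Markers of other cells were mostly low. Of the 12 fibroblast (feeder cell) genes 2 were expressed in all libraries: Fbln1, a matrix gene, at 57.7 ± 4.53 TPM and Pdgfrb at 1.53 ± 0.275, while Col1a1, a main collagen gene of fibroblasts chosen after its values were seen, stood at 0.610 ± 0.0964 TPM. Of the 13 genes of the 2-cell-like state 1 was expressed, Zscan4f at 2.57 ± 1.01 TPM, and reads of the near-identical Zscan4 copies cannot be assigned with certainty. Of 9 germline genes 8 were expressed, led by Dazl at 63.4 ± 5.52, Sycp3 at 16.6 ± 1.86 and Sycp1 at 14.9 ± 0.633 TPM.

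Regulators of chromatin, signalling and growth followed. All 12 Polycomb genes were expressed, with Eed at 288 ± 14, Suz12 at 225 ± 4.52 and Phf19 lowest at 4.00 ± 0.265 TPM. Of 9 DNA methylation genes 8 were expressed, with Uhrf1 at 240 ± 21.2, the maintenance methyltransferase gene Dnmt1 at 111 ± 9.06 and Tet3 lowest at 1.29 ± 0.279 TPM. The LIF and STAT3 list was expressed in full (5 of 5), with the feedback inhibitor gene Socs3 at 138 ± 8.53 and Stat3 at 65.8 ± 3.44 TPM. All 7 WNT targets were expressed, led by Cdx1 at 137 ± 8.41 TPM. Among 7 FGF and ERK targets 4 were expressed, with Etv5 at 95.1 ± 5.29 and Egr1 at 0.173 ± 0.102 TPM. Of 15 cell cycle genes 12 were expressed, among them Ccnd3 at 497 ± 15.8 and Cdk1 at 396 ± 13.4 TPM, and Cdkn2a was lowest at 0.400 ± 0.210. The glycolysis genes were all expressed (11 of 11), led by Aldoa at 2527 ± 71.7 and Pkm at 1814 ± 25.7 TPM. Of 11 p53 and stress genes 8 were expressed, with Bax at 395 ± 20.2 and Trp53 at 252 ± 8.26 TPM, and the heat shock gene Hspa1a stood at 0.333 ± 0.0651. The housekeeping genes were expressed in full (8 of 8), with Ppia at 3805 ± 54.6 and B2m lowest at 16.3 ± 2.77 TPM.

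Of 19 imprinted genes 12 were expressed, led by Snrpn at 167 ± 9.17, Rian at 115 ± 9.05 and Gnas at 105 ± 5.40 TPM, and Igf2 had 0 counts. In the X inactivation centre Rlim stood at 28.6 ± 1.92 TPM, Tsix (ENSMUSG00000085715.2, chromosome X) at 2.79 ± 0.715 and Xist, the RNA that silences the inactive X (ENSMUSG00000086503.4), at 0.263 ± 0.0723 TPM on 69 counts in total. Tsix and Xist overlap on opposite strands, so their reads are uncertain without the strand setting. Ftx stood at 1.60 ± 0.0700 TPM, and at 184 ± 5.18 TPM in the kallisto-style tables. All 5 Y chromosome genes had 0 counts in the RSEM-style tables, while the kallisto-style tables gave Uty 1.37 ± 0.406 TPM and Kdm5d 0.432 ± 0.0415 TPM. There Ddx3y stood at 0.0300 ± 0.0260, Eif2s3y at 0.00706 ± 0.0122 and Zfy1 at 0 TPM. The median TPM of 462 X-linked protein-coding genes was 0.804 ± 0.0251 of that of 11434 autosomal ones. This SD covers libraries only. The X median was 14.7 ± 0.368 TPM, and medians of single autosomes ran from 15.1 ± 0.430 (chromosome 1) to 20.8 ± 0.731 TPM (chromosome 8). Among genes with mean TPM of at least 5 the X to autosome ratio was 0.932 ± 0.0153.

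Of 10 abundant noncoding RNA genes 6 were expressed, led by the snoRNA host genes Gas5 at 526 ± 29.8 and Snhg1 at 157 ± 11.2 TPM, and Rmrp had 0 counts. Of 70 replication-dependent histone genes, whose main mRNAs end without a poly(A) tail, 13 were expressed, led by Hist1h2ah at 74.8 ± 17.5 TPM (42.4 ± 17.4 in the kallisto-style tables), with a list median of 0.538 ± 0.0379 TPM. The ERCC spike-ins took 4.96 ± 0.288% of TPM, and 51 of 96 had a TPM of at least 1 in all libraries.

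By correlation the replicates were close to each other, with the lowest of the 3 pairwise Pearson r of log2(TPM + 1) at 0.977 across 14912 genes, which are not independent replicates. The highest r was 0.979, and the Spearman rho was 0.927 for each pair. These values do not tell the pairs apart, although the counts set replicate 1 apart. Dispersion beyond the trend was found in 5 of 13391 genes by edgeR's quasi-likelihood fit with Benjamini-Hochberg adjustment, with 607 at an unadjusted p under 0.05. The long noncoding RNA gene Neat1 (ENSMUSG00000092274.3, chromosome 19, 5824708 to 5845478) had 105, 61.3 and 50.9 CPM in replicates 1, 2 and 3 (edgeR adjusted p = 0.0260), and did not pass without replicate 1 (adjusted p = 0.556), with ERCC scaling (0.176) or without the filter on low counts (0.459). Lars2, a mitochondrial leucyl-tRNA synthetase gene (ENSMUSG00000035202.8, chromosome 9, 123366927 to 123462666), had 595, 1516 and 1383 CPM (edgeR adjusted p = 0.000408), and did not pass with ERCC scaling (adjusted p = 0.0614). The others were mt-Co3 at 61.2, 210.1 and 262 CPM (edgeR adjusted p = 9.95e-05; 0.986 with kallisto-style counts), Gm42742 at 32.3, 33.2 and 5.54 CPM (edgeR adjusted p = 0.00218; 0.998 without replicate 3) and Gm14288 at 11.6, 1.05 and 10.4 CPM (edgeR adjusted p = 0.0260; 0.994 without replicate 2); the last 2 also failed with kallisto-style counts and without the filter, and Gm14288 with ERCC scaling. With kallisto-style counts, chosen after seeing the data, 16 genes passed, and Lars2 and Neat1 were the 2 shared with these 5. ERCC scaling left 2 genes, limma-voom gave 8, and leaving out replicate 1, 2 or 3 gave 17, 9 and 10. Among list members, Neat1 and mt-Co3 passed over all genes. Adjusted over the list alone, 1 core pluripotency gene passed (Pou5f1, 610.5, 431 and 442 TPM in replicates 1, 2 and 3). So did 1 WNT target (Axin2), 4 replication-dependent histones and 3 mitochondrial genes, mt-Co3 among them. These adjustments were not corrected for the number of lists, and over all genes Pou5f1 did not pass (edgeR adjusted p = 0.425).

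A spread beyond counting noise was found in 1656 of 13391 genes (12.4%). Without replicate 1 the number was 27, against 1464 without replicate 2 and 1471 without replicate 3. Replicates 2 and 3 had a mean chi-square of 1.37 per degree of freedom over 12584 genes, against 4.74 and 4.62 for the pairs with replicate 1. They were counted as separate replicates because the labels name them so, and a value above counting noise does not tell separate cultures from separate preparations of the same RNA. Across 7574 genes of at least 20 CPM, the log2 ratio of replicate 1 to replicate 2 rose with transcript length (Spearman rho 0.43 across genes), as did that of replicate 1 to replicate 3 (rho 0.38), against -0.09 for replicates 2 and 3.

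**Figure D2:**
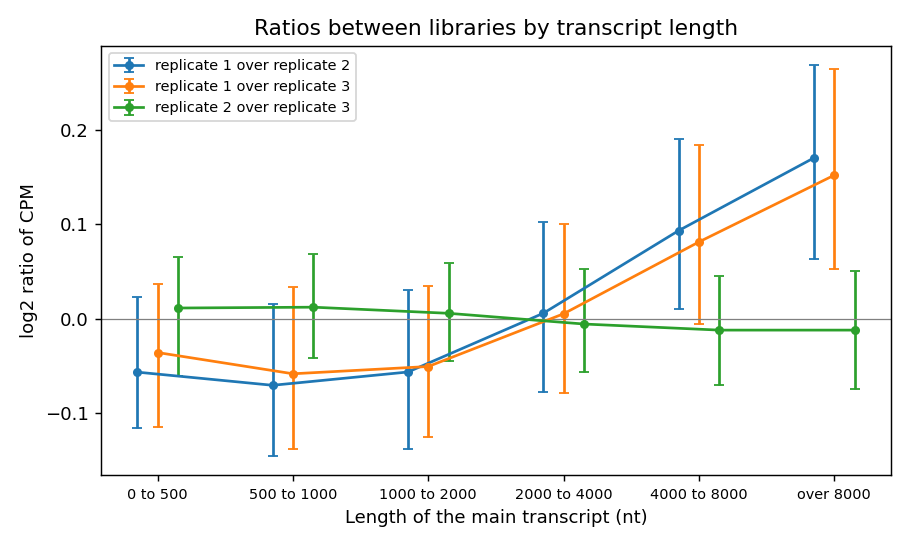
Median log2 ratio of CPM between libraries (vertical axis; bars give the quartiles over genes) by the length in nt of each gene's main transcript (horizontal axis), for the 3 pairs of replicates. In the longest class the medians are 0.17 and 0.15 for the pairs with replicate 1 and -0.01 for replicates 2 and 3.

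Of 28903 transcripts tested, 5551 were called by limma as differing between the 2 quantifications of each library, 3554 with higher kallisto-style and 1997 with higher RSEM-style TPM. An effective length of 0 in the RSEM-style tables, which rules out a value there, held for 154 of the 28903, all called, and without them 5401 of 28749 were called (a fit chosen after seeing the data). The microRNA transcript Mir6236-201 (123 nt) and the 57-nt transcripts Gm24270-201, Gm24245-201 and Gm23935-201 were listed at 0 in the RSEM-style tables, against 22976 ± 8821 TPM for the first and 22392 ± 9550 TPM for each of the others in the kallisto-style tables. The RSEM-style effective length of the first was 2.23 ± 0.0115 nt and that of the other 3 was 0, so their 0 values do not show absence. Their kallisto-style values are uncertain too: all are shorter than the mean fragment of 152 nt that the effective lengths imply there. Mir6236 had 9023, 20758 and 19590 kallisto-style counts in replicates 1, 2 and 3. Dock10-206, a retained-intron transcript, was also listed at 0 by RSEM and at 7457 ± 916 TPM by kallisto. In the other direction Gm10222-201 (663 ± 8.88 TPM), Rpl38-ps2-201 (567 ± 70.6) and Gm25745-201 (430 ± 127, on an effective length of 4.38 ± 0.0173 nt) were listed at 0 in the kallisto-style tables, and Fau-208 (764 ± 20 TPM) was close to 0 there. Of 18334 protein-coding transcripts 10.6% were called. Of the 109 microRNA transcripts tested, 61 had an effective length of 0. Without the minimum difference 17529 transcripts passed and 29.6% of them were higher in the kallisto-style tables, against 64.0% of the main calls.

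The main isoform was the same in both quantifications for 87.3% of 11374 genes with several transcripts. Pou5f1-201 took 99.8 ± 0.191% of Pou5f1 by RSEM and 99.5 ± 0.168% by kallisto, and Pkm-201 96.8 ± 0.280% and 96.5 ± 0.225%. Nanog-201 took 80.9 ± 1.84% and 84.5 ± 0.639%, and Mbd2-202 77.6 ± 1.64% and 79.3 ± 1.37%. Tcf7l1-201 led with 75.4 ± 3.02% and 81.3 ± 1.9%, and Dnmt1-201 with 66.8 ± 4.41% and 75 ± 1.54%. For Sall4 the RSEM-style tables split the gene between Sall4-202 (46.4 ± 1.86%) and Sall4-201 (45.1 ± 1.55%), and the kallisto-style tables put Sall4-201 first at 53.6 ± 0.860%. Dnmt3b was divided between Dnmt3b-208 (44.6 ± 12.4%) and Dnmt3b-201 (41.7 ± 4.23%) by RSEM, while the kallisto-style tables put Dnmt3b-201 first at 34.9 ± 14.3%, then Dnmt3b-208 at 32.3 ± 3.46% and Dnmt3b-202 at 16.03 ± 14.3%. Meg3-205 led Meg3 with 23.2 ± 4.50% and 30.9 ± 3.86%. Foxp1 and Xist were too low for stable shares, with Foxp1-204 at 29.0 ± 26.8% and Xist-201 at 68.9 ± 33.6% by RSEM (25.7 ± 8.73% and 100% by kallisto), and Sox2 has 1 transcript in the annotation.

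The kallisto-style tables held 1.81 ± 0.00550 times the counts of the RSEM-style tables. Among 29 spike-ins with at least 100 counts in each, the ratio had a median of 2.17 in the 6 shorter than 550 nt and 1.74 in the 15 of at least 1000 nt.

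**Figure D3:**
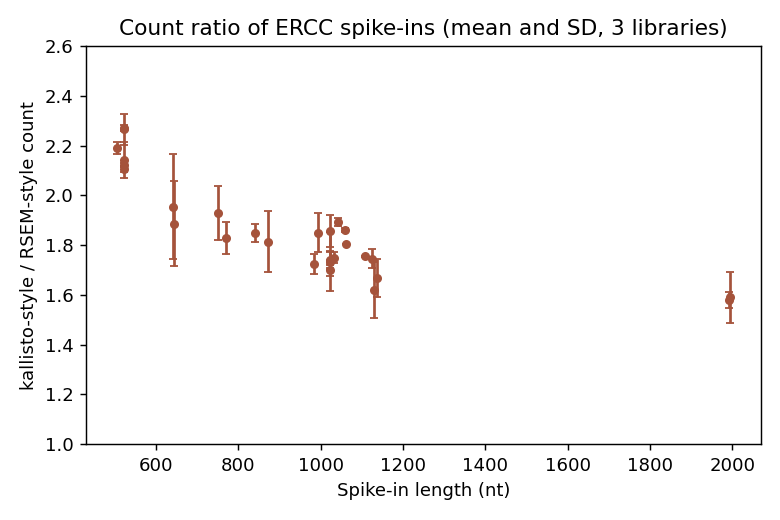
Ratio of kallisto-style to RSEM-style counts (vertical axis, starting at 1) against length in nt (horizontal axis) for the 29 ERCC spike-ins with at least 100 counts in each table; points and bars are the mean and SD over 3 libraries. The ratios run from 1.58 to 2.27 and are highest for the shortest spike-ins.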

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

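The rows with tRNA numbers, which no comparison uses, held 15.0 ± 1.97 estimated counts per library (SD, n = 3). This is a sum over 26248 rows, so the 3 counts that a count of 0 allows in a single row are no bound for it.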

How the results depend on the processing

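Both list differences kept their direction under every alternative run, between 6.73 and 9.18 for core pluripotency minus germ layers and trophoblast and between 5.05 and 5.86 for naive minus formative and primed. Expressed genes numbered 9775 to 16741 over the alternatives. Where a value moved, the cause was not tested. The lowest Pearson r was 0.942 with a pseudocount of 0.1, 0.987 over all genes above 0 and 0.976 to 0.978 with a replicate left out. Variable genes numbered 8 with limma-voom, 2 with ERCC scaling, 16 with kallisto-style counts (chosen after seeing the data) and 9 to 17 with a replicate left out. Over all alternatives the edgeR or limma-voom adjusted p of Lars2 ran from 5.66e-10 to 0.0614 and that of Neat1 from 2.49e-05 to 0.556. Genes beyond counting noise numbered 2800 with kallisto-style counts (also chosen after) and 27 to 1471 with a replicate left out, 27 being the value without replicate 1. The X to autosome ratio was 0.932 at a mean TPM of at least 5 and 0.851 over all gene types. Differing transcripts numbered 17529 without a minimum difference and 5401 at an effective length above 0 (chosen after), and 74.5% of calls were higher in the kallisto-style tables after centring (chosen after), against 64.0%. The main isoform was shared by 89.2% of genes at a mean TPM of at least 10, 87.5% of protein-coding genes and 86.8% to 87.2% of genes with a replicate left out. Spike-ins took 1.89% of estimated counts. Of 138 named genes, 93 moved by more than 1 SD with kallisto-style TPM, 106 of the 138 being lower there and 17 of those above 0 by RSEM moving over 1.5 times, and 81 when rescaled to nuclear protein-coding genes, which multiplies values by 1.2. Depth limits genes with few counts such as Fgf5.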

Other observations

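All tests below other than those of GC content and of the correlation with transcript length were chosen after the result was seen. No biological explanation was tested, since the design has 1 group.

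Lars2 was lowest in replicate 1, and so were the values of 4 genes chosen after their values were seen, none of which passed the edgeR test over all genes. The lincRNA genes Gm26917 and Gm42418, the first beside and the second overlapping the rRNA gene CT010467.1 on chromosome 17, had 2038, 3112 and 2948 CPM and 681, 950.4 and 905 CPM in replicates 1, 2 and 3. CT010467.1 had 706, 905 and 870.0 CPM, and the mitochondrial rRNA gene mt-Rnr1 had 35.0, 59.7 and 51.6. Mir6236, at 0 RSEM-style counts on an effective length of 2.23 nt, had 9023, 20758 and 19590 kallisto-style counts. The mitochondrial gene mt-Co3 and Gm28437, an unprocessed pseudogene on chromosome 1 chosen after its values were seen, moved in opposite directions: Gm28437 had 1203, 935 and 854 CPM in the RSEM-style tables, where mt-Co3 had 61.2, 210.1 and 262. In the kallisto-style tables mt-Co3 had 24016, 19826 and 20382 counts and Gm28437 201, 136 and 78.4. There both were highest in replicate 1, so the opposite movement was seen in the RSEM-style tables only. RSEM-style counts in replicates 1, 2 and 3 were 641, 1996 and 2600 for mt-Co3 and 12545, 8953 and 8516 for Gm28437. The RSEM-style tables thus put most counts on Gm28437 and the kallisto-style tables on mt-Co3. The variation of mt-Co3 alone is therefore uncertain, and whether the 2 genes share reads was not tested.

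Replicate 1 stood apart from replicates 2 and 3. Its depth was the highest, at 10425623 gene counts, which argues against low depth. The rho with GC content was 0.10 in both pairs with replicate 1, at the bound of 0.1 set beforehand and not below it by more than its spread; after removing a GC trend the spread of the log2 ratios was still at least 1.69 times that of replicates 2 and 3, which argues against GC as the whole difference, a reading chosen afterwards. Transcript length may be part of the difference, with rho of at least 0.383 in both pairs, but after a length trend was removed the spread was still at least 1.53 times that of replicates 2 and 3, so length is not all of it. Across 37 spike-ins the rho with length was 0.355 or higher in both pairs with replicate 1, with a bootstrap SD of up to 0.159. For replicates 2 and 3 it was -0.0118 (bootstrap SD 0.179). The spike-ins are too few to tell whether the length trend arose after they were added.

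Kallisto-style counts exceeded RSEM-style counts in all 3 libraries. A count of 1 strand alone would give ratios of 2 or more, and 72.4% of the 29 spike-ins had a ratio under 1.9, which argues against it. A loss of short fragments in the RSEM-style tables remains a candidate explanation: the ratio fell with spike-in length (Spearman rho -0.81 across spike-ins), and the effective lengths imply mean fragments of 206 ± 0.577 nt in the RSEM-style and 152 ± 0.824 nt in the kallisto-style tables (SD, n = 3).

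The median of the 70 replication-dependent histone genes lay near the floor, although the labels call the assay total RNA-seq and 13 of the 70 were expressed. This median reached at most 0.0888% of that of the 4 variant genes H3f3a, H3f3b, H2afz and H2afv, also chosen after their values were seen (671 ± 40.4 TPM, SD, n = 3). The sums lay closer together, at 270 ± 75.8 TPM for the 70 and 3174 ± 162 TPM for the 4 variants (SD, n = 3), so the share of 0.0888% holds for the median only. The kallisto-style median of the histones was at most 1.15 times the RSEM-style one, which argues, for the histones, against loss of reads with several matches in the alignments. Enrichment of RNA with poly(A) tails may account for the low histone median, as a hypothesis found and tested on the same data. The rRNA gene CT010467.1, at 784 ± 79.6 TPM, lay above the median of the histone variants, which does not decide for or against enrichment. Genes of the rRNA type together took 0.0784 ± 0.00796% of TPM, with CT010467.1 the only 1 of 354 expressed, and the mitochondrial rRNA genes 0.0199 ± 0.0029%. These shares leave out the lincRNA genes Gm26917 and Gm42418, beside or overlapping CT010467.1, at 1147 ± 226 and 691 ± 106 TPM.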
